A study of Arabidopsis thaliana with 12 samples.

How the data were processed

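RNA from mature Arabidopsis thaliana seed of the Landsberg erecta (Ler) background was measured on 12 Affymetrix ATH1 arrays, which carry 1 sample each. Per the labels' protocols, seed was taken from opened siliques, total RNA was prepared with a Qiagen column kit, and biotin-labelled RNA was made with the 3' IVT Express kit. The labels place 3 arrays in each of 4 groups and number them 1 to 3. Nothing in them says that the numbered samples came from separate plants or harvests, so the p-values measure only the spread between these samples, which may be technical.

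The deposited values are intensities on a linear scale, 1 signal per probe set and array, made with MAS5 in GCOS per the submitters' processing notes, which give no version. The mean of each deposited column without its lowest and highest 2% lay at 100, so each array's values are relative to its own trimmed mean. MAS5 subtracts a local background and a mismatch signal, and low values are noisy on a log scale for that reason. A change in the total amount of messenger RNA per seed cannot be seen after such scaling. Detection calls and scanner images were not used here.

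The table holds 22810 probe sets, of which 64 are AFFX control probe sets that stayed out of all gene tests. Intensities were log2-transformed with the deposited scaling kept. Of the 22746 remaining probe sets, the 9098 with a mean log2 value under the 40th percentile were not tested, which left 13648. The lowest mean tested was 2.88 on the log2 scale. Gene names came from the platform annotation given with the data and were updated through gene identifiers of the TAIR10.1 assembly. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 had none in that table. The 8730 are unnamed here, which does not mean that they lack a gene. A locus was found for 13436 of the single-gene probe sets. Genome coordinates are not printed because the build behind the probe annotation is not given in the sources used here. A gene with several probe sets was represented in gene lists by the one with the highest mean, and 146 genes had more than 1.

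Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with 1 coefficient per group was fitted to all 12 arrays, so that the groups share 1 estimate of the spread. Moderated statistics used an intensity-dependent variance prior, and p-values were two-sided and adjusted by the Benjamini-Hochberg method within each of the 6 comparisons. A probe set "rose" or "fell" where its adjusted p was under 0.05. Changes are log2 differences with their standard error (SE). Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 tested members, and again with an estimated correlation.

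Comparisons, gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. For each comparison against wild type at 20 °C in long days, the rule took the 10 largest rises and the 10 largest falls among probe sets that passed the test, had exactly 1 gene, and had all 3 arrays of one group above all 3 of the other. It added up to 4 members of each gene list by smallest adjusted p, and a set of genes fixed in advance. Of that set, the flavonoid genes DFR and BAN had a named probe set, and both were too dim to be tested. The lists covered dormancy and germination regulators, abscisic acid metabolism and signalling, gibberellin metabolism and response, flavonoids, cold response, late embryogenesis abundant proteins, storage and maturation, heat shock, clock and flowering, jasmonate, photosynthesis as a marker of green tissue, seed coat, endosperm, embryo epidermis and cytosolic ribosomal proteins. The lists for abscisic acid metabolism, gibberellin metabolism, jasmonate, seed coat, endosperm, embryo epidermis and cytosolic ribosomal proteins had 0 tested members and were not analysed here. The last was meant to use gene descriptions and drew on symbols and synonyms instead. Other lists were tested only in part, mainly because many members had no named probe set. Tested were 2 of 25 dormancy and germination regulators, 1 of 31 abscisic acid signalling genes and 5 of 16 gibberellin response genes. For cold response, late embryogenesis, storage and heat shock it was 3 of 20, 14 of 23, 5 of 28 and 5 of 18. For flavonoids, photosynthesis and clock genes it was 3 of 29, 6 of 38 and 1 of 37. A list result covers the tested members only.

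The alternatives tried were quantile normalization, centring on the array median, no filter on dim probe sets, a stricter filter at the 60th percentile, an offset of 16, no variance trend, array weights, a fit of only the groups compared, the replicate number as a block, a further requirement of a 2-fold change, and each array left out in turn. Scaling on the 18 hybridisation control probe sets, the mean of the 24 poly-A control probe sets as a covariate, and a spread estimated without ft-1 array 2 were added after the data had been examined. Families of genes and the pollen gene list were also chosen then. Shared controls were allowed for in part by 100 simulated sets of unchanged groups, with noise drawn independently for each probe set.

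The procedure was tested on simulated data with the residual spread of these arrays, 13648 probe sets and 200 changed ones in each of 3 runs. For the comparison of 10 °C with 20 °C, 42% of changes of 1 on the log2 scale and 76% of changes of 2 were recovered, with 8 false calls. The short-day run recovered 30% and 82%, with 8 false calls, and the ft-1 run 33% and 82%, with 9. The 14 tested late embryogenesis genes were shifted by 1 in each run as well. The noise was drawn independently for each probe set, so variation shared across a whole array was absent. The 200 changes are also far fewer than the 4347 calls at 10 °C. Recovery and false calls in the real comparisons may therefore differ from these values. The number of arrays limits the precision of every value.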

Results

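The series measured transcripts in mature seed from opened siliques to ask how the environment and genotype of the mother plant affect seed dormancy. The reference group was wild-type Ler grown at 20 °C in 16 h days (3 arrays). In the second group, wild-type plants were grown the same way to flowering and kept at 10 °C while seeds matured (3 arrays). In the third, wild-type plants grew at 20 °C in 8 h days (3 arrays). The last group carried the genotype ft-1, a mutation in a promoter of flowering, at 20 °C in 16 h days (3 arrays). For these 3 arrays, genotype and title give ft-1, but the source name is Glabra. The gene that carries the ft-1 mutation was not analysed here, so the label could not be checked against the data, and "ft-1" below means the arrays so labelled.

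Summed signals ranged from 3516240 to 4294740 over the 12 arrays. Across genes, arrays of 1 group correlated at r = 0.915 to 0.969 and arrays of different groups at 0.852 to 0.951. The lowest value within a group was that of ft-1 arrays 2 and 3. The first principal component held 39.7% of the variance and separated seed from 10 °C (45.8 to 85.9) from the reference (-40.3 to -32.8). On that axis ft-1 array 2 lay at 16.9, against -43.5 and -47.9 for the other ft-1 arrays. The poly-A control transcripts, bacterial RNAs that are added to a sample before labelling, were higher in seed from 10 °C (8.57 ± 0.395 on the log2 scale, SD, n = 3) than in the reference (6.82 ± 0.268, SD, n = 3). An exact permutation test of this difference of 1.76 gave a two-sided p = 0.1, the smallest that 3 against 3 arrays allow. The 3' minus 5' difference of the GAPDH control probe sets, a sign of RNA integrity, was 0.011 ± 0.125 (log2, SD, n = 3) at 10 °C and 0.372 ± 0.0829 (SD, n = 3) in the reference, with the same smallest p in the exact permutation test. For actin and ubiquitin the differences from the reference were -0.15 and -0.24 (exact two-sided p = 0.3 and 0.4).

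**Figure D1:**
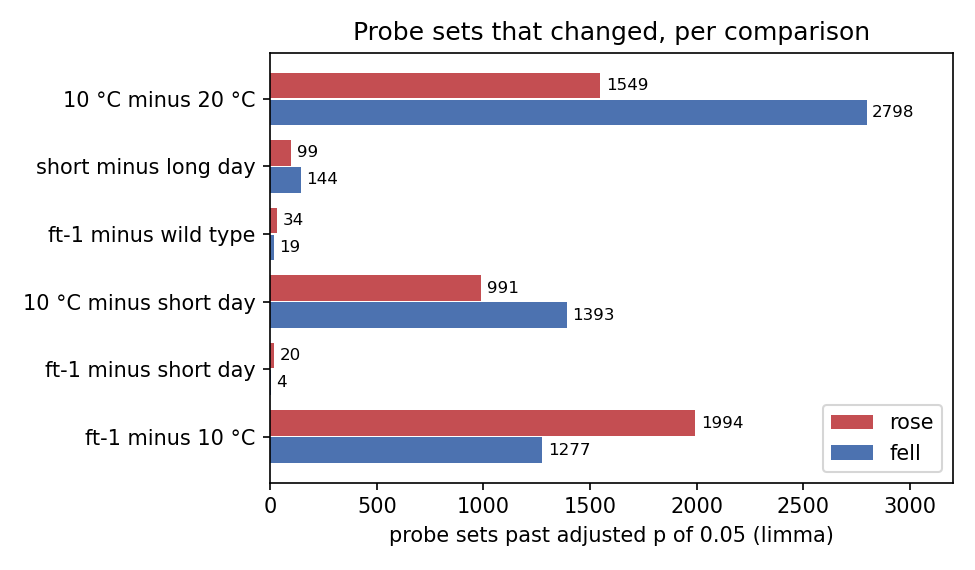
Number of probe sets past an adjusted p of 0.05 (limma), on the horizontal axis, for the 6 comparisons on the vertical axis. Red bars give probe sets that rose and blue bars those that fell, with 1549 and 2798 for 10 °C against 20 °C and 34 and 19 for ft-1 against wild type.

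The first comparison asked what a cool temperature during seed maturation changes. Seed that matured at 10 °C held far more transcript of AT3G62730 (log2 change 5.15, SE 0.35, adjusted p = 9.5e-07), of AT2G43590, a chitinase family gene (4.66, SE 0.27, adjusted p = 1.6e-07), and of SWEET7, from a family of sugar transporters (4.52, SE 0.78, adjusted p = 0.0013). The other named rises were AT4G10270 (4.72), AT1G54070 (4.41), AT2G18370 from the lipid transfer protein family (4.26), AT5G09480 (3.65), AT5G59530 (3.55), MSRB5, a methionine sulfoxide reductase (3.54), and AT5G55560 (3.44). The largest falls among probe sets with 1 gene were AT1G77550 (-6.31, SE 0.40, adjusted p = 3.2e-07), AT5G12400 (-5.23), AT3G52170 (-5.03), AT1G16830 (-4.88), AT5G39840 (-4.74) and AT5G54970 (-4.69). AT1G64190 (-4.32), AT1G68240, a bHLH transcription factor gene (-4.09), scpl35, a serine carboxypeptidase-like gene (-4.07), and AT1G76400 (-3.86) followed. AT1G68240 fell from a mean log2 signal of 9.16 to 5.07, while each of the other named falls had a mean in the cool group between -0.60 and 1.77. That is below the lowest mean tested (2.88), where values are noisy and the size and order of changes are uncertain. The same holds for the reference means of SWEET7, AT1G54070, AT5G09480 and AT5G59530. For each gene named by size, all 3 arrays of one group lay above all 3 of the other because the naming rule required it.

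Some cold response and seed maturation genes rose in this seed, and some of the latter fell. Of 3 tested cold response genes, the dehydrin gene LTI30 (0.81, SE 0.13, adjusted p = 0.00073) and the zinc finger gene STZ (1.27, SE 0.21, adjusted p = 0.0010) rose, and COR15B gave 0.00 (SE 0.38). Of 14 late embryogenesis abundant genes, whose products accumulate as seeds dry, 8 rose and 3 fell, or 11 and 3 adjusted over the list alone. M17 (1.38), AT3G22490 (1.04), M10 (0.64) and AT3G15670 (0.53) had the smallest adjusted p among those that rose, and AT2G42560 (-0.86), AT5G44310 (-0.78) and AT3G53040 (-0.54) were the 3 that fell. Of 5 storage and maturation genes, 4 rose over all genes and over the list alone: the oleosin gene AT3G01570 (0.72), the vicilin-like gene PAP85 (0.68), AT2G28490 (0.53) and AT1G03890 (0.47). Limma's camera gave an adjusted p = 0.016 for cold response, 0.00057 for late embryogenesis and 0.00090 for storage. With an estimated correlation all 3 gave an adjusted p = 0.088. Under quantile normalization the late embryogenesis list turned direction (median -0.14 against 0.45), and AT2G28490 and AT1G03890 changed sign (-0.04 and -0.15). The cold response list gave 0.39 and the storage list 0.87 as adjusted p under quantile normalization. With scaling on hybridisation controls the late embryogenesis and storage medians were -0.23 and -0.15.

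Of 5 tested heat shock genes, 4 rose in seed from 10 °C, also adjusted over the list alone: ATHSP22.0 (2.81, SE 0.53), AT1G52560 (2.25, SE 0.24), AT5G37670 (1.16, SE 0.26) and AT1G53540 (1.15, SE 0.33). The list's adjusted p was 0.00057 by camera, and 0.14 as an adjusted p with an estimated correlation. Of the 25 listed dormancy and germination regulators, 2 had a named probe set, and both were tested. AT4G18650 rose by 1.15 (SE 0.32, adjusted p = 0.014), and SPT gave -0.47 (SE 0.42, adjusted p = 0.42). EEL, a bZIP factor of abscisic acid signalling, gave -0.15 and the clock gene GI -0.06, neither past the test. None of 5 gibberellin response genes passed, with GID1A, a gibberellin receptor gene, at 0.31 and the cysteine protease gene CP1 at -0.93 (adjusted p = 0.95 for the list by camera).

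Flavonoid and photosynthesis genes went both ways at 10 °C. The flavonoid glycosyltransferase gene UGT78D1 rose (1.94, SE 0.58) from a reference mean of 2.38, below the lowest mean tested, while UGT78D2 (-0.80, SE 0.18) and the sterol glucosyltransferase gene UGT80B1 (-1.01, SE 0.24) fell, which gave an adjusted p = 0.53 for the list of 3, with a median of -0.80 and a mean of 0.05. DFR and BAN were too dim for a test. DFR had a mean log2 signal of 4.17 ± 0.441 (SD, n = 3) at 10 °C and 2.73 ± 1.43 (SD, n = 3) in the reference, and BAN 2.98 ± 1.65 (SD, n = 3) and 2.98 ± 0.881 (SD, n = 3). Of 6 photosynthesis genes, which would mark green tissue such as silique wall, LHCB4.2 (1.67, SE 0.18) and PSBW (1.74, SE 0.37) rose, and RCA (-1.98, SE 0.61) and LHCB4.1 (-0.61, SE 0.20) fell. The list gave an adjusted p = 0.38. With the poly-A level as a covariate LHCB4.1 gave 0.01.

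In all, 4347 of 13648 probe sets passed at 10 °C (limma, adjusted p under 0.05), of which 1549 rose and 2798 fell, and 2613 changed at least 2-fold. The 2 groups did not overlap for 48.0% of probe sets, against 10% by chance. The share that rose depended on the scaling. It was 35.6% as deposited, 63.6% after centring on the array median (2690 rose and 1538 fell) and 3.91% after scaling on hybridisation controls. The median change of all tested probe sets was -0.16, 0.19 and -0.85 under these scalings, so directions here are relative to the array's trimmed mean. Without cool array 1 the count was 2596, without cool array 3 it was 2669, and with the poly-A level as a covariate it was 423. Of 42 named genes that passed, 26 no longer passed with that covariate. Without reference arrays 1, 2 and 3, 5, 5 and 2 of the 42 no longer passed, and without cool arrays 1, 2 and 3, 5, 3 and 2.

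**Figure D2:**
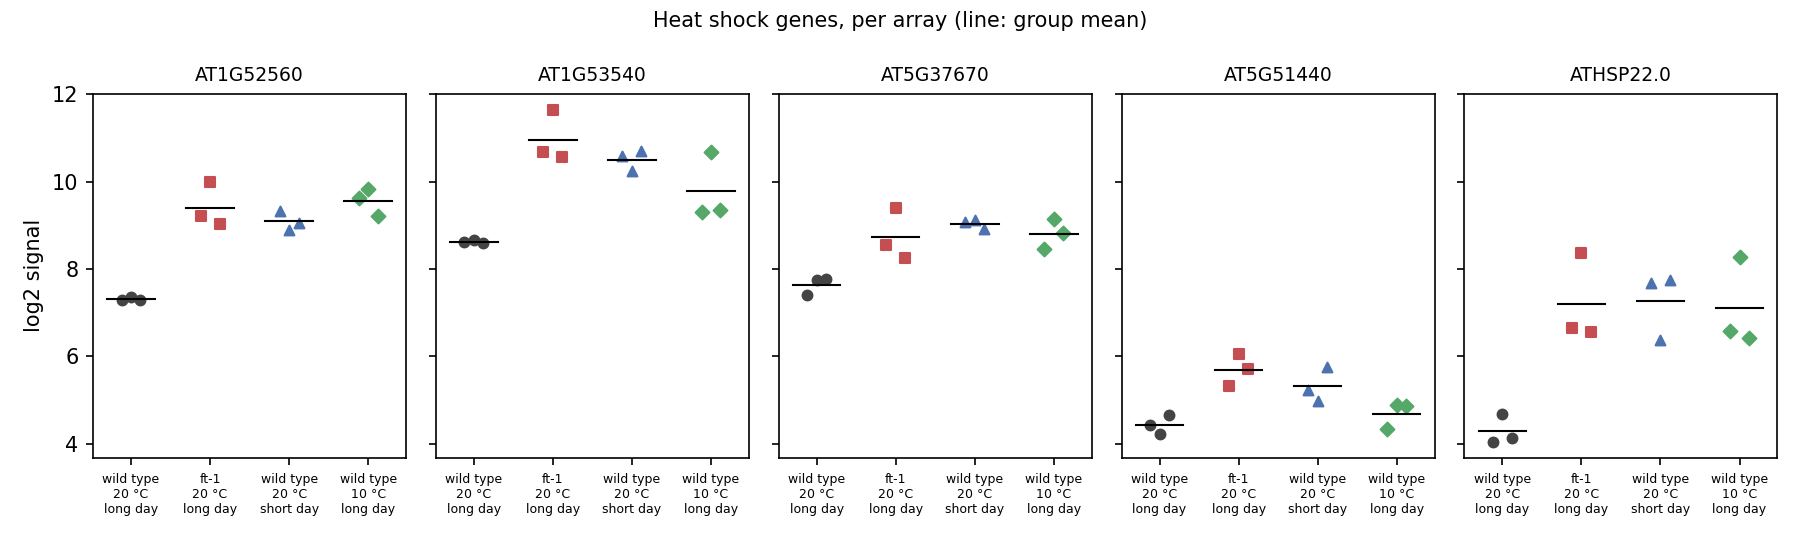
Log2 signal (vertical axis) of 5 heat shock genes, 1 panel each, in the 4 groups (horizontal axis). Points are single arrays and lines are group means of 3 arrays. The 3 reference arrays of AT1G52560 sit between 7.28 and 7.35, below the 9 other arrays.

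The second comparison asked what the mother plant's day length changes. Short-day seed differed from long-day seed in a smaller set of genes, with small heat shock protein genes among the largest rises of probe sets with 1 gene. ATHSP22.0 (2.98, SE 0.53, adjusted p = 0.011), AT1G53540 (1.88, SE 0.33, adjusted p = 0.010) and AT1G52560 (1.79, SE 0.24, adjusted p = 0.0023) rose. AT5G37670 rose by 1.38, which made 4 of 5 heat shock genes, or 5 adjusted over the list alone. Camera gave the list an adjusted p = 5.0e-09, and an adjusted p = 0.078 with an estimated correlation. AT3G07820, a polygalacturonase gene (3.45, SE 0.64), RALFL26, from a family of small peptide signals (3.67, SE 0.85), and AT2G47050, a pectin methylesterase inhibitor family gene (2.43, SE 0.49), rose as well. AT1G54070 (3.88), AT3G29375 (2.74), AT3G01240 (2.38) and AT3G09000 (1.75) complete the 10 largest rises among probe sets with 1 gene and no overlap between the groups. In the reference the means of AT1G54070 (SD 1.77, log2, n = 3), RALFL26 (SD 1.71, n = 3) and AT3G29375 (SD 0.831, n = 3) lay below the lowest mean tested, so the sizes of these rises are uncertain.

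Among the falls in short-day seed were AT5G42830 (-4.14, SE 0.82), AT4G39670 (-3.91, SE 0.73), scpl35 (-3.80, SE 0.86), AT2G16365 (-3.60) and AT5G05300 (-2.88). AT4G14930 (-2.78), AT5G46710 (-2.41), the cathepsin B-like protease gene AT4G01610 (-2.30), the metallothionein gene MT1C (-2.28, SE 0.36, adjusted p = 0.0052) and AT5G01210 (-2.28) followed. All of these except AT4G01610, MT1C and AT5G01210 had a short-day mean below the lowest mean tested (0.59 to 2.52), so their sizes and order are uncertain. MT1C rose at 10 °C (2.64, SE 0.36), and the direct comparison of 10 °C with short days gave 4.92 (SE 0.36, adjusted p = 1.9e-06). Of 14 late embryogenesis genes, M17 (0.55, SE 0.13) and AT3G22490 (0.67, SE 0.16) rose, the same number as over the list alone, with an adjusted p = 0.0026 by camera and an adjusted p = 0.22 with an estimated correlation. Under quantile normalization that list's median was -0.01 against 0.19 (adjusted p = 0.98), and without reference array 1 its adjusted p was 0.069. None of the storage, cold response, flavonoid, photosynthesis, gibberellin or dormancy genes tested passed over all genes. Adjusted over the list alone, OLEO3 (0.72) and AT3G01570 (0.39) of the storage list, UGT78D1 (1.62) and RCA (3.99-fold lower) passed. Camera gave storage an adjusted p = 0.052, which was 0.0037 without reference array 3 and 0.046 without short-day array 1, and photosynthesis 0.49, which was 0.0073 without reference array 3. AT4G18650 gave 0.17 (SE 0.32) and LTI30 0.15 (SE 0.13).

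In short-day seed 243 probe sets passed (99 rose and 144 fell), and the groups did not overlap for 30.3% of probe sets. The share that rose was 40.7%, 51.9% after centring on the array median and 7.52% with scaling on hybridisation controls, and poly-A controls were higher by 0.89 (log2) in these arrays. The count was 216 without reference array 3 and lower without any other: 76 and 78 without reference arrays 1 and 2, and 64, 121 and 70 without short-day arrays 1, 2 and 3. A fit of only the 2 groups gave 1107, and a spread estimated without ft-1 array 2 gave 1139. Of 23 named genes that passed, 14, 14 and 3 no longer passed without reference arrays 1, 2 and 3, and 16, 13 and 15 without short-day arrays 1, 2 and 3.

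The third comparison asked what the ft-1 genotype of the mother and seed changes. Of 5 tested heat shock genes, 3 rose in seed labelled ft-1, with AT1G53540 (2.33, SE 0.33, adjusted p = 0.0069), AT1G52560 (4.28-fold, SE 0.24 on the log2 scale, adjusted p = 0.0015) and ATHSP22.0 (2.91, SE 0.53, adjusted p = 0.030) past the test. All 5 list members passed when adjusted over the list alone. Camera gave an adjusted p = 3.3e-12, and an adjusted p = 0.034 with an estimated correlation. AT2G29500, a small heat shock protein gene (1.21), AT1G71000 (1.41), AT3G16120 (1.25) and the linker histone gene HIS1-3 (1.32, SE 0.24) rose too. AT1G54070 (18.4-fold), AT3G07820 (3.22) and AT2G47050 (2.95) were the largest rises among probe sets with 1 gene. The SD of AT1G54070 over the ft-1 arrays was 1.80, and its reference mean lay below the lowest mean tested.

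Only 9 falls met the rule in ft-1 seed. They were the alpha-tubulin gene TUA6 (-2.92, SE 0.52, adjusted p = 0.024), AT5G62720 (-2.03, SE 0.24), AT1G25530 (-1.80), AT4G33400 (-1.54), the beta-glucosidase gene BGLU25 (-1.39), AT1G33110 (-1.31), AT1G61740 (-1.24), the peroxidase gene AT1G71695 (-1.23) and LCR69, a defensin-like gene (-1.01). The ft-1 mean of TUA6 was 0.98 (log2), below the lowest mean tested. HIS1-3 fell at 10 °C (-1.89, SE 0.24) and LCR69 rose there (1.32, SE 0.20). The direct differences of ft-1 from 10 °C seed were 3.20 (adjusted p = 2.0e-06) for HIS1-3 and -2.33 (adjusted p = 6.4e-06) for LCR69. The 6 photosynthesis genes had a median of -0.94 (camera adjusted p = 0.019, and an adjusted p = 0.33 with an estimated correlation). The camera adjusted p was 0.063 without reference array 1, 0.14 without reference array 2, 0.062 without ft-1 array 3 and 0.086 with the poly-A covariate. Of these genes, RCA (-2.17), PSBY (-1.56) and PSAE-1 (-1.56) passed when adjusted over the list alone and none over all genes, and the ft-1 mean of PSAE-1 (2.66) was below the lowest mean tested. No late embryogenesis, storage, cold response, flavonoid, gibberellin or dormancy gene passed over all genes. Over the list alone UGT78D1 (1.58) passed. EEL (-0.48) did not pass over all genes. It was the only tested abscisic acid signalling gene, so its list gives no separate adjustment and no call was drawn from it.

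In ft-1 seed 53 probe sets passed (34 rose and 19 fell), with no overlap for 18.0% of probe sets. The count is not stable: it was 0 in a fit of only the 2 groups (1314 at an unadjusted p under 0.05, limma), 12 without the variance trend, and 1767 with array weights. The share that rose was 64.2%, 55.6% with scaling on hybridisation controls (20 rose and 16 fell), 46.8% with array weights, 39.1% without ft-1 array 2 (36 rose and 56 fell) and 38.2% with the poly-A covariate, which gave 1058 calls (404 rose and 654 fell). The count was 92 without ft-1 array 2, 85 without ft-1 array 3 and 28 without ft-1 array 1. Without reference arrays 1, 2 and 3 it was 15, 13 and 89. Of 19 named genes that passed, 13, 14 and 6 no longer passed without these reference arrays, and 11, 3 and 1 without ft-1 arrays 1, 2 and 3.

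The remaining comparisons set the 3 treated groups against each other, without the reference arrays except in the shared spread. They reuse the arrays of the first 3 comparisons, so they are not independent of those. Seed from 10 °C and short-day seed differed in 2384 probe sets (991 rose and 1393 fell), where 2 of 3 cold response genes, LTI30 and STZ, rose. Camera gave that list an adjusted p = 0.024, and an adjusted p = 0.22 with an estimated correlation. In the same comparison 3 of 14 late embryogenesis genes rose and 1 fell (3 and 2 adjusted over the list alone, adjusted p = 0.024). Of 5 storage genes 1 rose (4 adjusted over the list alone, adjusted p = 0.024), and of 6 photosynthesis genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.039). These 3 lists gave an adjusted p = 0.27 with an estimated correlation. Seed labelled ft-1 differed from 10 °C seed in 3271 probe sets (1994 rose and 1277 fell), and from short-day seed in 24 (20 rose and 4 fell). Of the 24, 5 have a single gene: TUA6 (-2.84) and AT5G38170 (-2.32) fell, while AT5G05300 (2.71), AT5G66440 (1.29) and AT1G17860 (1.21) rose. They are named because of their small number, after their values were seen. The short-day mean of AT5G05300 (1.31) and the ft-1 mean of TUA6 lay below the lowest mean tested. The late embryogenesis and storage lists had medians of -0.13 and -0.18 in ft-1 against short-day seed (adjusted p = 0.0066 and 0.023 by camera, and an adjusted p = 0.33 for both with an estimated correlation). No member of either passed over all genes, and 1 late embryogenesis gene and 0 storage genes fell adjusted over the list alone.

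Of the lists, 4 were lower in ft-1 than in 10 °C seed by camera. In the cold response list 2 of 3 genes fell (adjusted p = 0.018), and in the storage list 4 of 5 (adjusted p = 0.0017), the same numbers as adjusted over the list alone. Of 14 late embryogenesis genes 8 fell and 2 rose (9 and 3 adjusted over the list alone, adjusted p = 0.0017), and of 6 photosynthesis genes 3 fell (4, with 1 rise, adjusted over the list alone, adjusted p = 0.0099). With an estimated correlation photosynthesis gave an adjusted p = 0.15 and the others an adjusted p = 0.11. The direct list tests were not repeated under the alternatives.

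In these direct comparisons, centring on the array median turned the share that rose from 41.6% to 61.9% for 10 °C against short days and from 61.0% to 36.6% for ft-1 against 10 °C. For ft-1 against short days it was 83.3% and 72.2%. Scaling on hybridisation controls gave 9.03%, 95.2% and 96.8% in the same order, and the poly-A covariate 43.8%, 45.4% and 41.7%. The count for 10 °C against short days was 1063 and 1113 without cool arrays 1 and 3, and 1212, 1567 and 1197 without short-day arrays 1, 2 and 3. For ft-1 against 10 °C it was 1659, 5123 and 1729 without ft-1 arrays 1, 2 and 3, and 1811 and 1827 without cool arrays 1 and 3. For ft-1 against short days it was 7, 633 and 10 without ft-1 arrays 1, 2 and 3. Without short-day arrays 1, 2 and 3 it was 0, 13 and 10 (limma).

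The 3 effects against the reference were compared across 13648 probe sets, which are not independent replicates. The short-day and ft-1 effects correlated at r = 0.67, the 10 °C and short-day effects at 0.50, and the 10 °C and ft-1 effects at 0.37. Without ft-1 array 2 the first value was 0.44 and the last 0.092, and the last was 0.14 with the poly-A covariate and 0.18 with array weights. The jackknife SEs of the 3 correlations, from leaving out each of 9 arrays in turn, were 0.23, 0.071 and 0.29 in the order above. All 3 effects share the same 3 reference arrays, and 100 simulated sets of unchanged groups gave a mean r of 0.50 for each pair. The simulated noise was independent between probe sets, so it lacks variation that runs across a whole array. The simulated values therefore allow for the shared reference only in part. The covariances were 0.205, 0.274 and 0.182, against simulated means of 0.0809, 0.0807 and 0.0810. Of the probe sets that passed, 26 rose and 9 fell in both short-day and ft-1 seed, where independent lists would share 0.25 and 0.20. Short-day and 10 °C seed shared 67 rises and 64 falls (11.2 and 29.5 for independent lists), and 10 °C and ft-1 seed 23 and 7 (3.86 and 3.90). Calls in opposite directions numbered 0 for short days and ft-1, 19 for short days and 10 °C, and 5 for 10 °C and ft-1. At most 1 probe set was called in both in a simulation, but unchanged groups leave hardly any calls to share, so that value gives no measure for lists of these lengths. The 3 reference arrays cannot be split into parts of 2, so part of the excess may come from the shared controls. In all 3 comparisons 18 probe sets rose and 5 fell, among them ATHSP22.0, AT1G52560, AT1G53540, AT1G54070 and AT3G07820, which rose, and AT5G62720, AT4G33400 and AT1G61740, which fell.

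**Figure D3:**
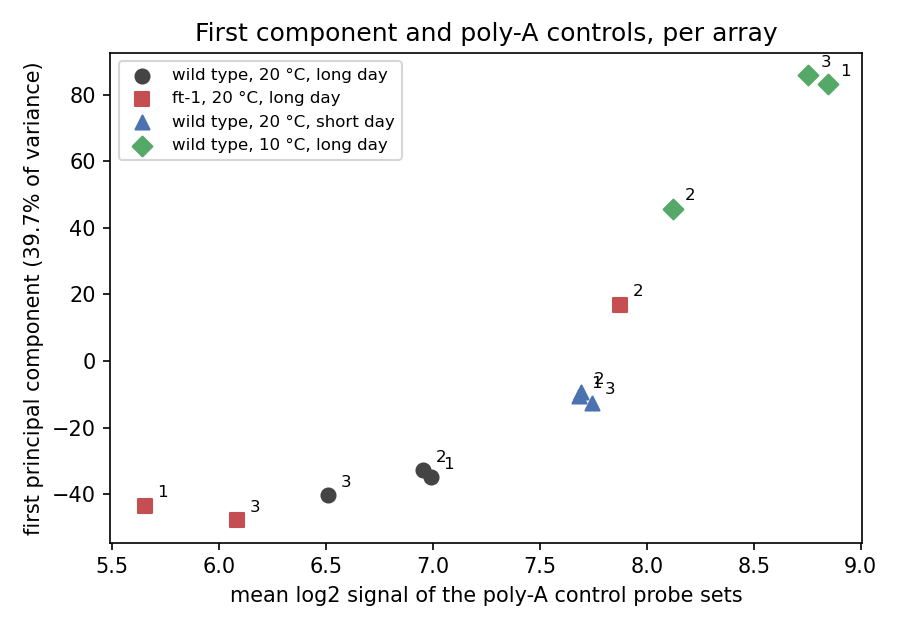
Position of each of the 12 arrays on the first principal component (vertical axis, no unit) against the mean log2 signal of the poly-A control probe sets (horizontal axis). Numbers are the replicate numbers of the labels. Array 2 of ft-1 lies at 16.9 and 7.87, apart from ft-1 arrays 1 and 3.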

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

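The test of the first component against the poly-A controls within groups and that of the pollen genes without ft-1 array 2 were chosen only after the result was seen. Some control probe sets, which were kept out of the gene tests, carried signal above every reference array in some groups. Hybridisation controls were higher by 0.69 (log2) in seed from 10 °C and by 0.28 in short-day seed. Poly-A controls were higher by 1.76 and 0.89 in the same groups. The probe set for 25S ribosomal RNA was higher by 1.501 in seed from 10 °C, and its signal was 24.9 in ft-1 array 1.

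Variation between arrays followed the poly-A control level. Within groups, deviations of the first component correlated with deviations of that level at r = 0.94 (exact within-group permutation p = 0.036) and rho = 0.92 (permutation p = 0.035). With ft-1 arrays 1 and 2 left out of the correlation, r was 0.92. The group means still included these 2 arrays, so that value is not free of them. With the level as a covariate, the median change of the probe sets called at 10 °C was 0.53 of its unadjusted size (0.44 to 0.55 with single arrays left out). As the whole cause, the level was predicted in advance to leave almost none of the change, and the range does not meet that. The bound set in advance for arguing against this cause was 0.5, which the range spans. How much of the change comes from the level therefore cannot be told apart from a temperature effect. Calls fell from 4347 to 423 as the median absolute change went from 1.12 to 0.58 and the median SE from 0.28 to 0.34, and a lower share of messenger RNA in total RNA, a different amount of added control and the temperature itself stay open.

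Of 5 heat shock genes, 4 rose in seed from 10 °C, 4 in short-day and 3 in ft-1 seed, and the list's adjusted p with an estimated correlation was 0.14, 0.078 and 0.034. A single odd reference array is argued against, since the lowest list median with 1 reference array left out was 1.15 (log2). All 9 other arrays had a list mean above every reference array. In the direct comparison of 10 °C with short days the list median was -0.22 (camera adjusted p = 0.66), with no gene past the test. For ft-1 against short days it was 0.31 (camera adjusted p = 0.58), also with none. For ft-1 against 10 °C it was 0.09 (camera adjusted p = 0.50), where 2 of 5 genes rose. A difference of the 3 reference arrays as a batch cannot be told apart from an effect of growth conditions, because the design has no second reference group. Temperature, day length and genotype stay open as untested biological explanations.

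Pollen-type genes were among the largest rises of probe sets with 1 gene in short-day and ft-1 seed. A candidate explanation is pollen RNA carried with the seed. Of 45 listed pollen genes, 16 had a named probe set, and 13 of these had not been seen when the list was written. The 13 had a median change of 0.85 (SE 0.42, 8 of 13 positive) in short-day and 0.95 (SE 0.48, 10 of 13) in ft-1 seed, and 1.12 (SE 0.31, 13 of 13) at 10 °C. Each SE of a median in this paragraph comes from the spread between genes measured on the same arrays. It treats the genes as independent and does not measure the spread between arrays. Of the 13, 6 were too dim to be tested. The other 7 had medians of 1.44 (SE 0.49, 6 of 7 positive) in short-day and 1.59 (SE 0.51, 6 of 7) in ft-1 seed. Without ft-1 array 2 the ft-1 median of the 7 was 1.24 (SE 0.33, 7 of 7). The filter took the mean over all 12 arrays, which favours genes that are higher outside the reference, so these 7 do not decide the question. The brightest, AT5G45880, had a mean of 6.81 in the reference and 7.66 and 7.76 in short-day and ft-1 seed. Array 2 of ft-1 alone cannot be told apart for ft-1 seed by the 13 genes. Without it their median was 0.82 (SE 0.47, 10 of 13 positive), above the bound of 0.5 by less than its SE. The short-day and ft-1 medians of the 13 over all arrays also lay above that bound by less than their SE. Pollen RNA, the shared reference arrays and a change of these genes within the seed stay open too.

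Other splits of the 6 arrays of each comparison number 10 with the real one, too few for a share under 0.05. A mixed split also puts any difference between the real groups into the spread, which lowers its count. Few calls there do not show what caused the difference. The real split gave 4347 calls for 10 °C against the reference and the highest other split 0, and 1 of the 10 splits gave as many. For short days the values were 243 and 0, and for 10 °C against short days 2384 and 0, each with 1 such split. For ft-1 against short days they were 24 and 10, and for ft-1 against 10 °C 3271 and 1757, with 1 split each. For ft-1 against wild type 2 of the 10 splits gave at least the real 53 calls. The other one, with 176 calls, exchanged ft-1 array 2 and reference array 3, and a split with several times the real count points to a structure of these samples other than the labels. That split set the arrays with the higher poly-A control levels (7.87, 6.99 and 6.96) against those with the lower (6.51, 6.09 and 5.65). Whether that level is the cause was not tested.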

How the results depend on the processing

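Scaling on hybridisation controls, the poly-A covariate and the spread without ft-1 array 2 were chosen after seeing the data, and the cause of a change was not tested unless named. Of the counts of calls under the alternatives, 52 lay within 1.5 times the reported one, 20 above and 39 below. Array weights gave 6549 calls for 10 °C against the reference, 2447 for short days, 1767 for ft-1, 4955 for 10 °C against short days, 2295 for ft-1 against short days and 6826 for ft-1 against 10 °C. Hybridisation control scaling gave 7183 for 10 °C, 399 for short days, 4242 for 10 °C against short days and 6456 for ft-1 against 10 °C. The poly-A covariate gave 423 for 10 °C, 148 for short days, 1058 for ft-1, 60 for ft-1 against short days and 724 for ft-1 against 10 °C. Without the variance trend, short days gave 139 and ft-1 gave 12. A fit of only the groups compared, with fewer arrays behind the spread, gave 1107 for short days, 0 for ft-1 (limma, 1314 at an unadjusted p under 0.05), 6 for ft-1 against short days and 1534 for ft-1 against 10 °C. The spread without ft-1 array 2 gave 1139 for short days and 3774 for 10 °C against short days. With no filter on dim probe sets, ft-1 against short days gave 15. The 2-fold requirement, which removes smaller changes by construction, left 2613 for 10 °C, 1421 for 10 °C against short days and 1981 for ft-1 against 10 °C. With single arrays left out, which leaves fewer samples, counts ranged from 2596 to 4738 for 10 °C, 64 to 216 for short days, 13 to 92 for ft-1, 1063 to 3005 for 10 °C against short days, 0 to 633 for ft-1 against short days and 1659 to 5123 for ft-1 against 10 °C. The correlation of the 10 °C and short-day effects was 0.60 with the stricter filter and 0.42 with the poly-A covariate. That of the 10 °C and ft-1 effects was 0.14 with the poly-A covariate and 0.18 with array weights, against 0.37, and that of the short-day and ft-1 effects ranged from 0.44 to 0.71 with single arrays left out. At 10 °C, hybridisation control scaling turned M10 to -0.043, AT3G15670 to -0.15, PAP85 to -0.0089, AT2G28490 to -0.15 and AT1G03890 to -0.22. This scaling lowers every change at 10 °C by the same 0.69, so it turns any rise smaller than that. Quantile normalization turned AT2G28490 to -0.036, AT1G03890 to -0.15 and the late embryogenesis list to a median of -0.14, and the poly-A covariate turned LHCB4.1 to 0.0055. The replicate block gave 133 calls for short days, 22 for ft-1 and 11 for ft-1 against short days. The numbers were not taken as pairs, since 2 of 18 same-numbered pairs had a correlation of deviations over 0.1 (range -0.23 to 0.14) and 1 of 12 arrays correlated best with its own number. Signal over background limits probe sets near the lowest mean tested, 2.88 on the log2 scale.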

Other observations

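The gene families here were chosen after the data had been examined. Of 67 tested genes encoded in the plastid genome, 31 fell, 3 rose and 33 did not pass in seed from 10 °C, with a median of -0.65. The largest of the 8 with the smallest adjusted p were ndhI (-3.66, SE 0.45), a subunit gene of the plastid NADH dehydrogenase-like complex, and the ribosomal protein gene rpl14 (-3.02, SE 0.39). The RNA polymerase gene rpoA (-2.87, SE 0.44), the protease gene clpP (-1.83, SE 0.21) and the ATP synthase gene atpB (-1.50, SE 0.18) fell as well. Over 16 families, camera gave an adjusted p = 0.0020, and an adjusted p = 0.56 with an estimated correlation. The median was -0.55 with quantile normalization, -0.30 with median centring and -1.33 with hybridisation controls. For all tested probe sets it was -0.04, 0.19 and -0.85 in the same order. Median centring and hybridisation control scaling shift every change by the same amount, so the sign under them is no separate test of this family. In short-day and ft-1 seed none of the 67 passed (medians -0.22 and -0.01). Labelling from the 3' end of polyadenylated RNA captures plastid transcripts poorly, and these values share that limit.

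Some autophagy genes of the ATG family rose and some ubiquitin-specific protease genes (UBP) fell at 10 °C. The 8 tested ATG genes were ATG3 and forms of ATG8, so they do not represent autophagy genes in general. Of these, ATG3 (1.21, SE 0.20), ATG8G (1.06, SE 0.27) and ATG8C (0.60, SE 0.21) rose and none fell (median 0.68, camera adjusted p = 0.0054, and an adjusted p = 0.56 with an estimated correlation). With scaling on hybridisation controls, which lowers every change at 10 °C by the same 0.69, that median was -0.01. Of 12 UBP genes, 8 fell, among them UBP21 (-2.58, SE 0.69, to a mean below the lowest tested) and UBP16 (-2.15, SE 0.39), and none rose (median -0.92, adjusted p = 0.017, and an adjusted p = 0.56 with an estimated correlation). With the poly-A level as a covariate the UBP median was -0.02 (adjusted p = 0.75). In ft-1 seed the UBP median was -0.46 (adjusted p = 0.043, and an adjusted p = 0.87 with an estimated correlation), and 0 of the 12 passed (limma).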
